A study of Rattus norvegicus with 12 samples.

How the data were processed

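The series comprised 12 libraries from the lumbosacral spinal cord of fetal Wistar rats on embryonic day 17, 6 for lncRNAs and 6 for miRNAs, with 3 ARM and 3 normal libraries of each kind. Groups and replicate numbers were taken from the sample titles. The labels give the same short library names to lncRNA replicates 1 to 3 and to miRNA replicates 4 to 6. They do not say whether a shared name means shared RNA, nor from how many litters the samples came, so p-values measure the spread between these samples.

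The authors deposited 1 table per kind of RNA. The lncRNA table holds whole-number read counts and, per the file headers, FPKM values, with the transcript's name, length in bases and position. The deposited FPKM values equalled counts divided by length and by a library total, and the implied totals ran from 18945583 to 30430852, so that lncRNA counts made up 14.6% to 17.4% of them. The miRNA table holds whole-number counts and, per the file headers, TPM values, which equalled the row's share of the library's counts, on the usual TPM scale. The deposited counts were used as they stood, and the FPKM and TPM values entered no test. Per the submitters' processing notes, CASAVA 1.8, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff were used, with the mouse build mm10. The table's coordinates include 551 rows on a chromosome 20, which the mouse lacks, so they are not those of mm10, and the build is not given in the sources used here. The counting tool, the strand setting and the gene models are not given in the sources used here either. Coordinates are printed as deposited.

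Of the 22701 lncRNA rows 20717 had NONCODE identifiers, 985 Ensembl identifiers and 999 assembly identifiers. Gene symbols came from the names in the table, matched to the symbols and synonyms of the GRCr8 annotation table for 8464 rows (37.3%), 8370 of them to a coding gene. A transcript is called by its name in the table without the release suffix. No row lacked a name or identifier. All 22701 lncRNA rows had a count in at least 1 library, and 137 miRNA rows had none in any.

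Each comparison was fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM normalization, filterByExpr), with no covariate, and p-values were adjusted after Benjamini and Hochberg over all tested features of the table. Log2 fold changes are ARM minus normal, with the standard error from the F statistic. Levels are CPM on TMM-scaled library sizes, which were summed over the tested rows of the table. The design was fixed before the data were examined, including 18 miRNA lists, 6 lncRNA lists and 13 lists of coding genes by which transcripts are named. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01 and then an estimated correlation) and fry, adjusted over the lists of a family. A test of transcript classes and chromosomes was planned for 20 or more called transcripts and was not run.

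The rule for named features was also fixed beforehand. It took features past the threshold whose groups did not overlap, up to 12 per direction. Where fewer than 5 passed in a direction it added the 5 with the smallest unadjusted p. From each list it took the 3 members with the highest mean level and any that passed, and from each table the 8 features with the highest mean level, leaving out those without a symbol. Features named outside it, such as other rows of a called gene or those called by DESeq2, were chosen after their values were seen. The transcript called higher in ARM cord and 1 glial member are not reported here.

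Where a group had 0 counts, a lower bound of the fold was computed against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio has an exact 95% interval from the binomial share of counts. For a single library the floor of 3 counts came to 0.659 to 0.994 CPM in the lncRNA libraries and 0.227 to 0.26 CPM in the miRNA libraries. Reads carry no stated molecular identifiers, so bounds and intervals cover counting error only.

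The code was tested on counts simulated from the observed means, dispersions and library sizes, with 200 features changed 2-fold or 4-fold. Every changed feature that passed the adjusted threshold had the right direction, which was not checked for the others. There were 12 false calls among 13252 simulated lncRNAs and 3 among 511 simulated miRNAs. The 12 stood beside 3 and 74 recovered lncRNAs changed 2-fold and 4-fold, so false calls exceeded a share of 0.05 of the lncRNA calls. The 3 stood beside 80 and 94 recovered miRNAs. Pairs of libraries differed far more than sampling noise allows, with a chi-square per degree of freedom of at least 12.4, so no pair was counted as 1 sample. Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, leaving out each library, a 2-fold threshold, unadjusted p with a 2-fold threshold, and lncRNA rows summed by gene name. Alternatives written beforehand for normalized values did not apply, because counts were tested. As each miRNA name occurs once, nothing was summed there. Some predicted miRNAs with different names had identical values, at 6.50 ± 1.03 against 8.07 ± 1.65 CPM, so not every row was a separate feature. Library totals implied by the FPKM values and robust estimation were added after seeing the data.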

Results

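Long noncoding RNAs (lncRNAs) and microRNAs (miRNAs) were measured in the lumbosacral spinal cord of fetal rats on embryonic day 17. Fetuses with anorectal malformations (ARM), induced in the dam with ethylenethiourea, were compared with normal fetuses. The labels name no group exposed to ethylenethiourea without ARM, so effects of the exposure and of the malformation cannot be told apart. Each kind of RNA had 3 libraries from ARM cord and 3 from normal cord. The lncRNA table held 22701 transcript rows, with total counts of 3017868, 4508920 and 4549756 in normal replicates 1 to 3 and of 3795224, 3666644 and 3299241 in ARM replicates 1 to 3. The miRNA table held 846 rows, 753 with a catalogue name and 93 predicted. Its total counts were 11526673, 12856194 and 12317421 in normal replicates 4 to 6 and 13233949, 12262705 and 12268404 in ARM replicates 4 to 6. Levels are given below in CPM, as the mean ± SD of 3 libraries, with the normal group first. CPM are counts relative to the library's scaled total over the tested rows of that kind of RNA.

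The first comparison asked which lncRNA transcripts differed between ARM and normal cord. Of 13584 tested transcripts, 6 were lower and 1 was higher in ARM cord at an adjusted p under 0.05 (edgeR quasi-likelihood test, n = 3 and 3). Other splits of the 6 libraries into 3 and 3 gave 3 to 10 calls, so the number of calls did not set the real split apart. The most abundant of the called transcripts was A2bp1.b, a noncoding transcript named after Rbfox1, which encodes a neuronal splicing regulator. It fell by 2.12 on the log2 scale (SE 0.11, adjusted p = 0.00194), from 1453 ± 78.8 to 334 ± 37.7 CPM. Most of the other lower transcripts were close to 0 in every ARM library. Nfe2l1.c, named after a transcription factor of the proteasome and oxidative stress responses, had 156, 200 and 254 counts in the normal libraries and 1 count in each ARM library.

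The 3 ARM counts of Nfe2l1.c gave a ratio of normal to ARM of 181, with a 95% exact counting interval of 61.8 to 882 (adjusted p = 1.66e-04). The transcript cheegar.a, which has no gene symbol, had 2 counts in each ARM library and 329, 390 and 313 in the normal libraries (adjusted p = 4.06e-04). The assembled transcript MSTRG.9781.2 had 1 count in the ARM group and 1109 in the normal group (adjusted p = 0.00868). Its ratio of 989 had a counting interval of 177 to 39097. NONRATT005158.2, with no symbol, had 0 counts in ARM cord and 188 in normal cord, at least 55.9-fold lower against a floor of 3 counts over the group (adjusted p = 0.032). Lca5.c, named after the gene of a ciliary protein, fell from 13.8 ± 1.44 to 0.866 ± 0.361 CPM (log2 fold change -3.97 ± 0.31, adjusted p = 0.0124). These intervals and bounds cover counting error only. Leaving out 1 library ended the call of NONRATT005158.2 (adjusted p = 0.105, 0.182 and 0.211 without normal replicates 1, 2 and 3), of Lca5.c (0.068 without normal replicate 3 and 0.0612 without ARM replicate 1) and of MSTRG.9781.2 (0.0777 without ARM replicate 3). Summed by gene name, MSTRG.9781 had a log2 fold change of -0.47 (adjusted p = 1.00). For Nfe2l1 the sum gave -2.81 (adjusted p = 0.00403), against -7.35 for the row Nfe2l1.c alone. Summed instead with the 2 lncRNA rows that overlap it, Nfe2l1.c gave 131 ± 16.7 against 79.2 ± 7.56 CPM, a 1.65-fold difference.

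In the coordinates of the deposited table, whose build is not given in the sources used here, A2bp1.b (NONRATT005197.2) lay on chromosome 10, 8312954 to 8371299, Nfe2l1.c (NONRATT005942.2) on chromosome 10, 84682448 to 84688899, and NONRATT005158.2 on chromosome 10, 110422967 to 110424759. The row cheegar.a (NONRATT012007.2) lay on chromosome 16, 54083152 to 54087424, and MSTRG.9781.2 on chromosome 16, 77737030 to 77757461. Lca5.c (NONRATT028821.2) lay on chromosome 8, 90930866 to 90931644. Other rows of the same genes did not pass the test. Nfe2l1.d was at 9.92 ± 0.798 against 8.47 ± 1.82 CPM and A2bp1.e at 16.5 ± 0.371 against 16.7 ± 3.51 CPM. The strand and exon structure of the rows are not given in the sources used here, so reads of overlapping or antisense transcripts cannot be told apart.

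**Figure D1:**
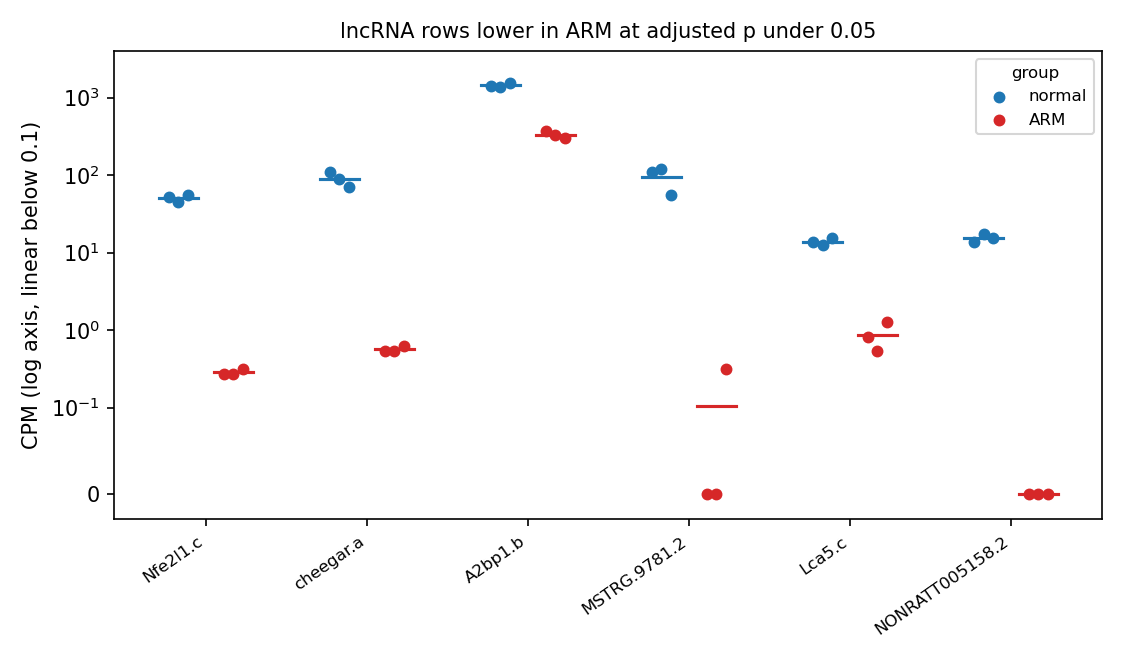
Levels of the 6 lncRNA transcripts past the threshold that were lower in ARM cord, in CPM on a log axis that is linear below 0.1. Each point is a library, each bar the mean of 3, with normal cord in blue and ARM cord in red. A2bp1.b lay between 1387 and 1540 CPM in normal cord and between 299 and 374 in ARM cord, while NONRATT005158.2 was at 0 in the 3 ARM libraries.

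As fewer than 5 transcripts passed as higher in ARM cord, the 4 with the next smallest p in that direction are given as values that did not pass in the main edgeR fit. In the order of p, 6 transcripts lower in ARM cord lay between the called ones and the last of these 4. DESeq2 called 3 of the 4, MSTRG.21280.23 (adjusted p = 5.82e-09), Hist1h2ail.a (2.36e-06) and Bcl7b.a (0.0286), and edgeR called Bcl7b.a without ARM replicate 3 (0.0263). Bcl7b.a (chromosome 12, 24543745 to 24548614) had 3 counts in normal cord and 59 in ARM cord, a ratio of 22.1 with a counting interval of 7.19 to 110.0 (adjusted p = 0.241). With rows summed by gene name, Bcl7b had a log2 fold change of -0.0067. MSTRG.21280.23 (chromosome 7, 33004033 to 33011348) was at 173 ± 67.8 against 739 ± 231 CPM, with a log2 fold change of 2.09 ± 0.37 (adjusted p = 0.952). A transcript listed as TLV_coat.3.a (chromosome 1, 213709555 to 213724761) had a log2 fold change of 1.52 ± 0.28 (adjusted p = 0.997). For Hist1h2ail.a (chromosome 17, 43633689 to 43634462), named after a histone gene, the log2 fold change was 4.18 ± 0.79 (adjusted p = 0.997).

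Among lncRNAs known by name, no row of the imprinted Meg3, the neural Miat or the snoRNA host genes passed the test. Meg3 supplied all 12 rows of the imprinted list. Of its 10 tested rows 8 had a positive and 2 a negative log2 fold change, with a median of 0.04, and none passed over all transcripts or adjusted over the list alone (camera adjusted p = 0.18). Its 3 highest rows, RGD1566401.b, .i and .j, were at 12899.9 ± 436 against 13356 ± 2263, 6277 ± 495 against 6279.9 ± 601 and 700.5 ± 72.2 against 662 ± 24.1 CPM. The miRNA host list held the same tested rows and gave the same values. The list's camera result passed without ARM replicate 2, at an adjusted p of 0.00904, and with DESeq2 statistics, at 0.0283, both with the preset correlation. In the main fit the estimated correlation of the Meg3 rows was 0.26, which gave an adjusted p of 0.637. Without ARM replicate 2 the estimated correlation gave 0.239 and fry 0.00953. Miat was at 7206 ± 973 against 7510.2 ± 832 CPM, and it was the sole tested member of both the nuclear and the neural list (log2 fold change 0.06 ± 0.13). The 12 tested snoRNA host rows, of Gas5, Snhg8 and Snhg11, split into 6 positive and 6 negative, with a median of -0.05 (camera adjusted p = 0.986). Examples were Snhg11 rows RGD1563912.a at 663 ± 127 against 579 ± 36.9 and RGD1563912.e at 72.4 ± 6.56 against 73.5 ± 11.7 CPM, and Gas5.a at 128 ± 18.4 against 116 ± 11.9 CPM. No row matched the list of Hox antisense and intergenic lncRNAs.

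Transcripts named after developmental genes of the spinal cord gave no list that passed, and none of their members passed over all transcripts. Such a transcript says nothing of the messenger RNA itself. For Hox genes, which set position along the body axis, 3 of 5 tested rows were positive (median 0.11, mean -0.04). Hoxb8.a was at 359 ± 31.9 against 391 ± 11.4, Hoxd9.b at 132 ± 22.8 against 146 ± 4.098 and Hoxb3.c at 89.6 ± 8.44 against 96.5 ± 12.1 CPM. For motor neuron genes, 4 of 5 were negative with a median of -0.18. Etv4.d was at 28.2 ± 5.15 against 24.9 ± 4.83, Nefh.b at 16.2 ± 14.96 against 15.4 ± 19.3 and Foxp1.c at 11.7 ± 6.27 against 15.2 ± 5.65 CPM, and the list passed without ARM replicate 1 (median -1.14, camera adjusted p = 0.016 with the preset correlation and 0.409 with an estimated one). For progenitor and interneuron factors 5 of 7 were negative (median -0.09), with Sox21.a at 50.9 ± 2.17 against 45.4 ± 9.96, Tlx3.a at 21.9 ± 0.888 against 19.8 ± 2.26 and Dbx2.a at 14.5 ± 0.481 against 14.4 ± 1.49 CPM. The 2 tested rows of patterning signals were Gli3.a at 6.002 ± 2.703 against 4.598 ± 0.221 and Dll1.b at 2.34 ± 1.04 against 3.898 ± 1.29 CPM (median 0.14). Without normal replicate 1 this list had enough members for a set test and passed in the opposite direction (median -0.70, camera adjusted p = 0.00601 with the preset correlation and 0.372 with an estimated one). The 5 axon guidance rows had a median of 0.19, and Robo3.b was at 66.5 ± 29.96 against 75.8 ± 8.74, Slit3.b at 17.9 ± 1.297 against 13.4 ± 5.13 and Sema6a.c at 7.68 ± 2.03 against 9.99 ± 2.01 CPM.

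The 4 glial rows had a median of 0.20, with Nfib.b at 301 ± 90.3 against 351 ± 86.98 and Slc1a3.b at 14.2 ± 4.42 against 13.3 ± 5.86 CPM. The 6 rows of apoptosis and stress genes had a median of 0.08, and Mdm2.c was at 19.2 ± 7.57 against 20.2 ± 2.68, Ddit3.b at 17.8 ± 4.09 against 18.9 ± 4.18 and Trp53.g at 9.15 ± 4.95 against 9.84 ± 1.51 CPM. Ethylenethiourea also acts on the thyroid, and the 3 tested rows of thyroid axis genes had a median of 0.07. Reln.d was at 199 ± 4.19 against 209 ± 26.1, Thra.c at 47.1 ± 6.44 against 45.9 ± 0.975 and Thra.b at 3.55 ± 0.394 against 4.15 ± 0.206 CPM. Over these developmental lists the camera adjusted p ran from 0.239 for motor neuron genes to 0.924 for Hox genes and axon guidance.

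Among markers of other tissues, Hbb.d, a row named after beta globin, stood out in a single library. It had 675 counts in ARM replicate 3 and 7 to 16 in each of the other 5 libraries (log2 fold change 4.75 ± 1.74, adjusted p = 1). The row was the sole tested one of the blood list, so it passed over the list alone only because its edgeR p of 0.0306 stayed unadjusted. Pou4f1.b, of sensory ganglion neurons, was present in all 6 libraries, at 525 ± 24.9 against 562 ± 78.1 CPM. For cartilage and meninges, 4 of 5 rows were positive (median 0.21, camera adjusted p = 0.7), and Col2a1.a was at 15.5 ± 26.7 against 11.7 ± 10.4, Col1a1.c at 12.6 ± 3.81 against 14.5 ± 5.55 and Col3a1.b at 6.495 ± 2.24 against 6.58 ± 0.685 CPM. For endothelium and microglia Pecam1.a was at 28.1 ± 5.04 against 37.6 ± 4.28 and Csf1r.d at 3.05 ± 1.504 against 2.82 ± 1.48 CPM. No row of the muscle list was tested. The named transcripts with the highest levels in the table were Meg3 row RGD1566401.b, the RNA component of the mitochondrial RNA processing enzyme RNase MRP at 9569.5 ± 2005 against 11393 ± 2269.8 CPM, Miat, and Nrep.b at 7029.6 ± 278 against 7089 ± 849 CPM.

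In all, 407 transcripts (3.00%) had an unadjusted p under 0.05, against 679 that a uniform distribution gives. Leaving out 1 library gave 348 to 741, with 741 against 714 expected without ARM replicate 3. Other splits of the 6 libraries into 3 and 3 gave 400 to 1292. The 1292 came from normal replicates 1 and 2 with ARM replicate 3 against the rest. Groups did not overlap for 1057 transcripts (7.78%), where chance gives 10%. With the replicate number as a block 2 transcripts passed, DESeq2 called 18, and leaving out 1 library gave 10 to 18, with 18 without normal replicate 1 and without ARM replicate 3. Of counts simulated at these depths the test recovered 3.33% of transcripts changed 2-fold and 75.5% of those changed 4-fold. The same simulation gave 12 false calls beside the 3 and 74 transcripts recovered.

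The second comparison asked which miRNAs differed between ARM and normal cord. Of 525 tested miRNAs none passed an adjusted p of 0.05 (edgeR quasi-likelihood test, n = 3 and 3), 31 had an unadjusted p under 0.05 where 26.2 were expected by chance (18 to 40 with 1 library left out, below the expected number without normal replicate 4 and without normal replicate 6), and DESeq2 called 7. Other splits of the 6 libraries into 3 and 3 gave 9 to 39 miRNAs with an unadjusted p under 0.05. The lowest adjusted p belonged to 2 miRNAs of one X-linked cluster and to a predicted miRNA. The level of miR-450b-5p was 414 ± 9.103 against 524 ± 9.84 CPM (log2 fold change 0.34 ± 0.06, adjusted p = 0.0937) and that of miR-450a-5p 692 ± 8.28 against 866 ± 24.1 CPM (0.32 ± 0.06, adjusted p = 0.0937). Both were higher in 3 of 3 ARM libraries than in all normal ones. The lumbosacral cord was dominated by miR-9a-5p, a miRNA of neural progenitors, which took 31.4% to 33.1% of the counts of a library (log2 fold change 0.07 ± 0.04, adjusted p = 0.934).

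The other miRNAs with the smallest p in each direction are given as values that did not pass. Higher in ARM cord were miR-675-5p, which is cut from the imprinted H19 transcript, at 0.707 ± 0.148 against 1.86 ± 0.168 CPM (log2 fold change 1.39 ± 0.29, adjusted p = 0.243), miR-542-3p (0.43 ± 0.11, adjusted p = 0.598) and miR-200a-3p (2.81 ± 0.84, adjusted p = 0.598). Predicted miRNA 76 of the deposited table had 0 counts in ARM cord and 45 in normal cord, at least 15.2-fold lower against a floor of 3 counts over the group (adjusted p = 0.0937). Lower in ARM cord were miR-218a-5p, a motor neuron miRNA (-0.28 ± 0.08, adjusted p = 0.598), miR-33-5p (-0.50 ± 0.15, adjusted p = 0.598), miR-221-3p (-0.20 ± 0.07, adjusted p = 0.633) and miR-129-5p (-0.21 ± 0.08, adjusted p = 0.65). The level of miR-218a-5p was 19874 ± 1167 against 16369.9 ± 1444 CPM, lower in each ARM library than in each normal one.

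DESeq2 called miR-450a-5p, miR-450b-5p, miR-542-3p, miR-183-5p, miR-429 and miR-292-5p higher and predicted miRNA 76 lower. Without ARM replicate 6, the edgeR test called miR-200a-3p, miR-200b-3p and miR-429 higher, at log2 fold changes of 3.33, 3.20 and 3.29 and adjusted p of 0.00123, 0.00124 and 0.00132.

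Among the lists fixed before the data were examined, epithelial miRNAs and the miR-183/96/182 cluster stood highest in ARM cord. All 8 tested epithelial members had a positive log2 fold change, with a median of 2.35, and 4 passed when adjusted over the list alone (camera adjusted p = 6.82e-06). With an estimated correlation the list did not pass (adjusted p = 0.431). The summed level of the 8 miRNAs was 383 CPM in ARM replicate 4, 609 in ARM replicate 5 and 92.2 in ARM replicate 6, against 116, 175 and 139.5 in the normal libraries. The level of miR-203a-3p was 99.1 ± 17.9 against 151 ± 120.1 CPM, that of miR-205 22.8 ± 8.54 against 85.7 ± 90.5 and that of miR-200a-3p 7.78 ± 2.06 against 54.7 ± 45.2. All 4 tested members of the list of sensory neuron and cilia miRNAs were positive, from 0.54 to 0.62 with a median of 0.58, and all 4 passed when adjusted over the list alone (camera adjusted p = 3.37e-06, or adjusted p = 0.431 with an estimated correlation). The estimated correlation of these 4 miRNAs was 0.91, so they are not 4 separate observations. Their levels were 5201 ± 1055 against 7928 ± 2078 CPM for miR-182, 2163 ± 348 against 3327 ± 840.0 for miR-183-5p and 688 ± 121.8 against 999 ± 267 for miR-96-5p. The summed level of these 4 in ARM replicate 5, 8804 CPM, lay within the normal range of 7125 to 9811 CPM. Neither list passed with fry, which tests whether the members move one way (adjusted p = 0.71 for each). Without ARM replicate 6 the epithelial list passed both, at an adjusted p of 0.0165 with an estimated correlation and 0.0193 with fry.

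**Figure D2:**
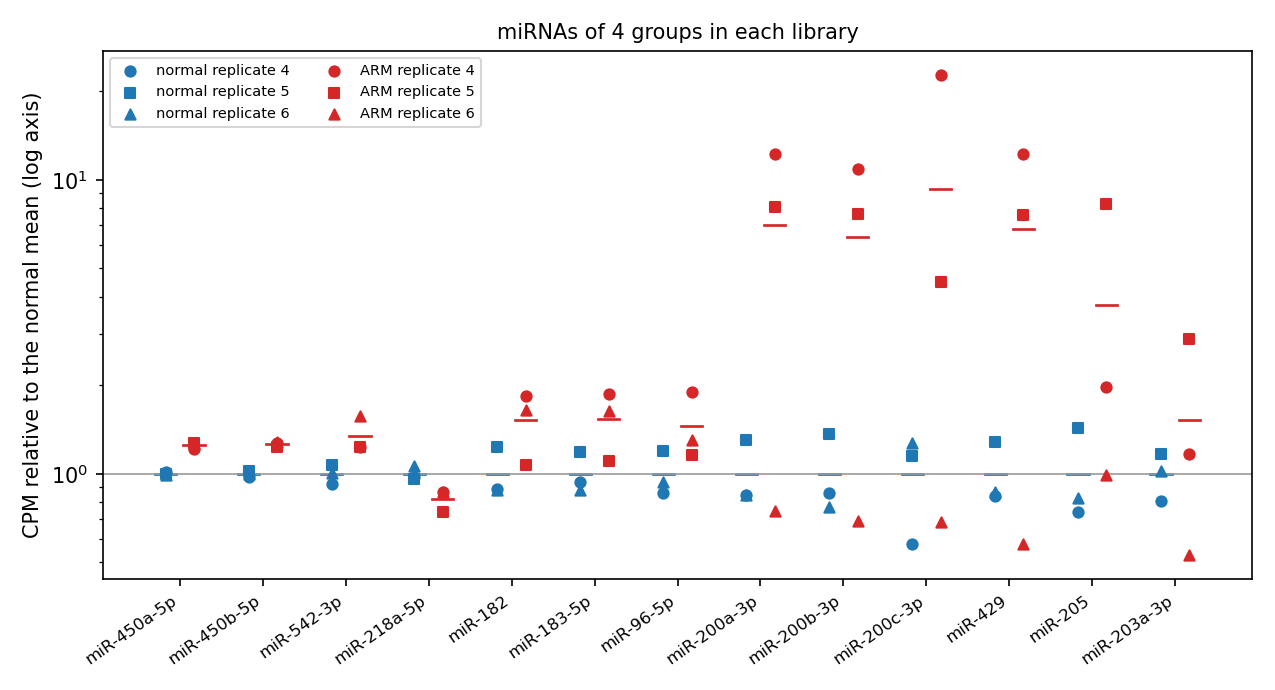
Level of 13 miRNAs in each library divided by the mean of the 3 normal libraries, on a log axis. Circles, squares and triangles stand for replicates 4, 5 and 6, with normal cord in blue, ARM cord in red and a bar at each group's mean. The miR-200 family members were high in ARM replicates 4 and 5 and below the normal mean in ARM replicate 6.

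No list of neuronal, progenitor or glial miRNAs passed. In the neuron-enriched list 23 of 37 members were negative (median -0.06, camera adjusted p = 0.0568), while the mean was 0.03, with miR-184 as the highest member at 3.73. With miRNAs of every count kept, that list passed at an adjusted p of 0.0341, with DESeq2 statistics at 0.0261, with robust estimation at 0.0493 and without normal replicate 5 at 0.0481, all with the preset correlation. With an estimated correlation the adjusted p was 0.503 with every count kept, 0.596 with robust estimation and 0.432 without normal replicate 5. In the main fit it was 0.622, and fry gave 0.71. Its most abundant members were miR-7a-5p at 16029.9 ± 771 against 15101 ± 1255, miR-128-3p at 7038 ± 740.7 against 6825 ± 556 and miR-124-3p at 2118 ± 343 against 1812 ± 255 CPM. Both tested motor neuron members were negative, with miR-218a-2-3p at 2.304 ± 0.354 against 1.81 ± 0.385 CPM, and miR-218a-5p passed when adjusted over the list alone. With miRNAs of every count kept, the motor neuron list had enough members for a set test and passed with the preset correlation (median -0.36, camera adjusted p = 0.0243), but not with an estimated one (adjusted p = 0.503). In the progenitor list 11 of 16 were negative (median -0.06). Its top members were miR-9a-5p at 316411 ± 6728 against 331442 ± 8981, miR-181a-5p at 12648 ± 658 against 12098 ± 257 and miR-9a-3p at 6888 ± 488 against 6758 ± 92.1 CPM. In the miR-17/92 family 16 of 22 were positive (median 0.06), with miR-25-3p at 3276 ± 271 against 3655 ± 693, miR-93-5p at 2439 ± 144.3 against 2564 ± 322 and miR-20a-5p at 2325 ± 143 against 2484 ± 424 CPM. The 6 oligodendrocyte members had a median of -0.02, with miR-219a-2-3p at 2634 ± 143.8 against 2732 ± 199, miR-219a-1-3p at 156 ± 17.9 against 146 ± 6.03 and miR-338-5p at 90.3 ± 11.2 against 90.2 ± 5.09 CPM.

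The miRNAs of the Hox clusters, the let-7 family and the imprinted Dlk1-Dio3 cluster had medians within 0.02 of 0 on the log2 scale. For the 11 Hox-cluster miRNAs the median was -0.01, with miR-10a-5p at 103648 ± 3758 against 103268 ± 11536, miR-10b-5p at 21476 ± 496 against 21668 ± 859 and miR-196a-5p at 1571 ± 193 against 1554 ± 276 CPM. For the 18 let-7 members it was -0.02, with let-7i-5p at 32539 ± 1133 against 33514 ± 3161, let-7c-5p at 21091 ± 1091 against 20054 ± 1039 and let-7g-5p at 14004 ± 271 against 14173 ± 891 CPM. The 82 tested Dlk1-Dio3 miRNAs split into 41 positive and 41 negative, beside the median of 0.04 of the Meg3 rows of the same locus. Among them miR-127-3p was at 22775 ± 914 against 23507 ± 2361, miR-379-5p at 4334 ± 253 against 4471 ± 344 and miR-434-5p at 4031 ± 124 against 4018 ± 303 CPM. The other most abundant miRNAs were miR-99a-5p at 91158 ± 4491 against 90713 ± 1202, miR-125b-5p at 31326 ± 2797 against 30473 ± 894 and miR-100-5p at 22901 ± 1339 against 23464 ± 608 CPM.

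For other tissues, muscle miRNAs had a median of -0.02 over 5 members, with miR-499-5p at 109 ± 19.05 against 94.1 ± 2.83, miR-206-3p at 46.1 ± 29.7 against 53.3 ± 20.5 and miR-1-3p at 10.4 ± 5.18 against 11.2 ± 4.198 CPM. Vascular miRNAs had a median of 0.04 over 6, with miR-126a-3p at 10140 ± 274 against 9853 ± 641, miR-143-3p at 8542 ± 422 against 9601 ± 526 and miR-126a-5p at 328 ± 12.8 against 291 ± 30.9 CPM. Leukocyte and microglial miRNAs had a median of -0.03 over 5, with miR-146a-5p at 427 ± 43.02 against 443 ± 74.7, miR-150-5p at 80.1 ± 8.57 against 69.1 ± 6.85 and miR-155-5p at 9.82 ± 0.761 against 9.596 ± 2.99 CPM. The 9 miRNAs of cartilage and mesenchyme had a median of -0.06 and a mean of 0.19. Among them miR-199a-3p was at 2008 ± 74.2 against 1849 ± 375, miR-199a-5p at 1978 ± 171 against 1897 ± 262 and miR-140-5p at 382 ± 15.3 against 381 ± 26.1 CPM, and miR-675-5p passed when adjusted over the list alone. For this list camera pointed up, against its median. Over 4 members, the liver, gut and kidney list had a median of 0.15, with miR-192-5p at 325 ± 58.6 against 324 ± 71.7, miR-194-5p at 164 ± 19.7 against 173 ± 33.8 and miR-122-5p at 6.66 ± 8.79 against 12.9 ± 10.99 CPM.

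The p53 and apoptosis list had a median of 0.01 over 7 members, with miR-34c-5p at 269 ± 20.8 against 260.0 ± 7.47, miR-145-5p at 211 ± 17.01 against 212 ± 21.7 and miR-145-3p at 21.9 ± 2.32 against 23.05 ± 1.55 CPM. The hypoxia miRNA miR-210-3p was at 148 ± 7.33 against 185 ± 22.2 CPM (log2 fold change 0.31 ± 0.10) and passed when adjusted over its list of 2, whose other member miR-210-5p was at 1.68 ± 0.636 against 1.84 ± 0.192 CPM. No member of the erythroid list was tested. In the deposited table miR-451, miR-144 and miR-142 were listed at 0 in all 6 libraries. Whether they were removed before counting is not given in the sources used here, so these values were not read as levels. Of the miRNA lists with a set test that did not pass in the main fit with the preset correlation, the camera adjusted p ran from 0.0568 to 0.893.

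The self-test on simulated counts recovered 84.2% of 95 miRNAs changed 2-fold and 97.9% of 96 changed 4-fold. These made up a large share of the 511 simulated miRNAs, which makes the adjusted threshold easier to pass. The recovered shares therefore do not give the power to find a few changed miRNAs. Across the 525 miRNAs 45 (8.57%) had groups that did not overlap, where chance gives 10%.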

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

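Library totals implied by FPKM and robust estimation were chosen after seeing the data. The 7 called lncRNAs were the same 7 with RLE size factors, with the implied totals, with robust estimation and with a 2-fold threshold. Without the filter 6 of them passed, and with rows summed by gene name 5 of their genes, when MSTRG.9781 was among those that no longer passed because other rows of the gene joined the sum. DESeq2 called 18 lncRNAs, all 7 among them, the replicate block left 2 (Nfe2l1.c and cheegar.a), an unadjusted p with a 2-fold threshold gave 134, and leaving out 1 library gave 10 to 18, with 5 to 7 of the 7 kept. NONRATT005158.2 lost its call without any one normal library, Lca5.c without normal replicate 3 or ARM replicate 1, and MSTRG.9781.2 without ARM replicate 3. The count of 0 miRNAs held with RLE size factors, no filter, the block, robust estimation and a 2-fold threshold. DESeq2 called 7, an unadjusted p with a 2-fold threshold gave 11, and leaving out 1 library gave 0 to 3. The cause of the differences between the tools was not tested. Libraries that share a number deviated from their group means with correlations of -0.060 to 0.029 for lncRNAs and -0.13 to 0.027 for miRNAs, so the numbers were not taken to pair samples, and not every library correlated best with its own number. No A2bp1.b call was lost except under the block (adjusted p = 0.147). Without the filter on low counts the median log2 fold change became 0.14 for snoRNA host genes, -0.034 for patterning signals, -0.24 for sensory ganglion genes, -0.16 for cartilage and meninges and -0.013 for Dlk1-Dio3 miRNAs. Summed by gene, the snoRNA host median was 0.089 and the log2 fold change of Bcl7b was -0.0067. Under the block the muscle miRNA median was 0.0097. Leaving out 1 library turned the sign of further medians that had not passed. The patterning list passed below 0 without normal replicate 1 with the preset correlation (camera adjusted p = 0.00601), but not with an estimated one (0.372). The ranges were -0.074 to 0.32 for apoptosis genes, -0.14 to 0.41 for axon guidance, -0.0070 to 0.23 for cartilage and meninges, -0.11 to 0.35 for endothelium and microglia, -0.051 to 0.29 for glia, -0.70 to 0.39 for patterning signals, -0.13 to 0.072 for progenitor factors, -0.016 to 0.16 for the thyroid axis, -0.037 to 0.13 for the imprinted and the miRNA host lncRNAs, -0.040 to 0.16 for Miat and -0.14 to 0.14 for snoRNA hosts. Among miRNA lists they were -0.045 to 0.078 for Dlk1-Dio3, -0.11 to 0.062 for Hox clusters, -0.059 to 0.015 for let-7, -0.17 to 0.14 for leukocytes, -0.12 to 0.024 for oligodendrocytes, -0.021 to 0.092 for p53, -0.21 to 0.36 for muscle and -0.024 to 0.11 for vessels. In the lncRNA test 3.33% of simulated 2-fold changes were recovered, and depth, spread and the number of tests were not separated.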

Other observations

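The tests of reads moved within a locus and of X-linked miRNAs were chosen after the result was seen. Some miRNAs stood out in a single ARM library. In ARM replicate 4, miR-184 was at 47.3 CPM, against 3.48 and 1.52 in ARM replicates 5 and 6 and 0.462 to 2.69 in normal cord. Of the embryonic miR-290 cluster, miR-293-5p was at 49.8 CPM in that library and at 2.53 to 4.85 in the other 5, and miR-292-5p at 15.2 and 0.938 to 2.45 CPM. The X-linked miR-741-3p, outside the miR-450 cluster, had a log2 fold change of 1.85 (adjusted p = 0.598), from 0.341 to 0.923 CPM in normal cord and from 0.98 to 3.96 CPM in ARM cord.

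In 5 of the called transcripts, each of the 3 libraries of one group had at most 2 counts and each of the other 3 at least 20. The real split of the 6 libraries held 5 such transcripts and the highest other split 8, and 4 of the 10 splits held as many as 5. The real split gave 7 calls and the highest other split 10, with as many in 5 of the 10 splits. Neither number set the real split apart from the others, and 10 splits are too few for a share under 0.05. Pairs of libraries of one group differed by a median of 202.5 such transcripts (183 to 220) and pairs across groups by 208 (183 to 232), which is consistent with differences between single fetuses or litters, such as inherited variants, though any other difference between libraries in how reads are assigned to transcripts would give the same. Reads moved to another lncRNA row of the locus would leave the locus sum in place, but it still differed 1.65-fold for Nfe2l1.c. The sum holds lncRNA rows only, so reads moved to a coding transcript of the locus would not be seen. For MSTRG.9781.2 the ratio was 1.39 with ARM libraries that spread more widely than the level lost, and cheegar.a and NONRATT005158.2 had no overlapping row.

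The epithelial miRNAs were high in ARM replicates 4 and 5, and in ARM replicate 6 they summed to 92.2 CPM, below the normal range of 116 to 175 CPM. Epithelial tissue in the dissection is a candidate explanation, since the miR-200 family is typical of epithelia, and lncRNA replicates 1 and 2 carry the library names of miRNA replicates 4 and 5. In lncRNA rows named after epithelial genes (9 rows for 6 of 40 marker genes, 4 of which had counts in every normal library), the sum was 35.1 CPM in ARM replicate 1 and 24.5 in ARM replicate 2, against 16.9 to 26.3 in the other 4 libraries. The most abundant row, of Spint2 (NONRATT002479.2), had 50 and 38 counts in ARM replicates 1 and 2 and 23 to 54 in the others. Lsr had 13 and 14 against 9 to 29, and the other Spint2 rows 21 and 11 against 15 to 25, and 12 and 5 against 6 to 7. The remaining rows, with fewer counts, each peaked in ARM replicate 1 or 2. Esrp1 had 0 and 12 counts against 0, and Llgl2 17 and 0 against 1 to 4. The Krt19 rows had 9 and 4 against 0 to 3, and 7 and 1 against 0 to 2. Elf3 had 2 and 6 against 0 to 3. These few counts leave epithelial tissue in the dissection open. They also leave open an effect of ethylenethiourea or of the malformation on some fetuses, which was not tested.

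The miRNAs miR-322, miR-351, miR-503, miR-542, miR-450a and miR-450b, clustered on the X chromosome, had positive log2 fold changes for 10 of 11 tested members, with a median of 0.26. They ran from -0.12 for miR-351-3p to 0.51 for miR-542-5p, with miR-322-5p at 0.13, miR-503-3p at 0.10 and miR-503-5p at 0.09. The cluster was chosen after its values were seen, so the count of positive members is no independent support. A shift of X-linked miRNAs at large would move those outside the cluster too. The 37 other X-linked miRNAs had a median of -0.018 (quartiles -0.13 and 0.13), with 18 positive, which argues against such a shift. It does not exclude a different mix of sexes, which need not move X-linked miRNAs at large and was not tested. A specific difference of this cluster in ARM cord may remain, as a hypothesis found on these data, since no other technical explanation was tested. No miRNA passed the adjusted threshold in the real split of the 6 miRNA libraries or in any other (highest 0, so all 10 splits gave as many), and 10 splits cannot give a share under 0.05.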
